A study of Mus musculus with 8 samples.

How the data were processed

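RNA was sequenced from cells sorted as CD8 T cells from B16 tumours of wild-type C57BL/6 and Cd36 knockout mice, per the labels' protocols, which name total RNA and standard Illumina library preparation. How many animals entered each library, the read layout and the sorting gates are not given in the sources used here. The 8 samples are titled as lanes 1 to 4 of 1 library number per genotype, so they were treated as 4 lanes of 1 library per genotype, and lanes were summed. The genotype of each sample came from its label.

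Each file gives, per transcript, estimated counts that need not be whole, TPM (transcripts per 1000000) and an effective length. Per the submitters' processing notes, kallisto was used with genome build GRCm38.p6, and DESeq2 is named there too. Versions are not given in the sources used here. The deposited estimated counts were not normalised, and 33.5% to 35.1% of the values per lane were not whole. The deposited TPM values, made by the authors with kallisto, are scaled for effective length and for the total of each lane. The effective lengths, per the file headers another kallisto output, were used only to derive the mean fragment length that they imply. Pseudoalignment divides reads among similar transcripts, so values of near-identical genes depend on that division. The strand setting is not given in the sources used here.

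Estimated counts of 142351 transcripts were summed over the 55335 genes to which the files assign them, then over lanes, and rounded to whole numbers. Gene coordinates came from GENCODE release M21 on GRCm38, in which 99.7% of gene identifiers of the files had a match. The annotation release that the authors used is not given in the sources used here. The libraries held 10071960 and 10363391 counts, from 2497048 to 2611740 per lane. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.934 for the WT library and 1.071 for the CD36_KO library. The main value was the log2 ratio of TMM-scaled CPM (counts per 1000000 of the scaled library size), CD36_KO over WT. Its 95% interval was an exact Clopper-Pearson interval of the share of a gene's counts found in 1 library, and covers counting error only. A gene was measured when its mean over the libraries was at least 5 CPM. It counted as at least 2-fold higher or lower when its log2 ratio was at least 1 in size and the interval excluded no difference. No p-value or standard error is given for the genotype, because lanes of 1 library do not measure variation between animals or preparations.

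Lanes were compared by a chi-square of gene counts over Poisson expectation. Per degree of freedom it was 1.29 over the WT lanes and 1.25 over the CD36_KO lanes, against 16.8 for a WT lane beside a CD36_KO lane. Over genes whose counts were whole in all lanes, a set chosen after seeing the data, it was 1.06, 1.05 and 19.2. Pearson correlation of log CPM across genes was 0.973 to 0.976 within a library and 0.854 to 0.857 between libraries, and genes are not independent replicates. Lanes of a library thus differed by little more than sampling noise. They were counted as 1 library because of their titles, whatever the outcome of this check.

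The gene lists, 30 in number, the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Cd36, then the 12 highest and 12 lowest protein-coding genes by log2 ratio among those that pass the 2-fold rule, have a mean of at least 20 CPM and go the same way in all 16 pairs of a WT lane with a CD36_KO lane. Immunoglobulin and T cell receptor segments, mitochondrially encoded genes and genes named only by a number were left out of that ranking. For each list it names up to 4 measured members with the largest absolute log2 ratio, the most abundant member of cell type lists, and Ifng, Tnf, Gzmb, Prf1, Pdcd1, Havcr2, Tox, Tcf7, Gpx4, Slc7a11 and Acsl4. Some genes that the rule names are not reported here. A hepatocyte list of 24 genes was added after the highest genes were seen, and Alb, Cd3e, Dct and Pmel were chosen for the level comparison after their values were seen. The lists covered T cell function, metabolism, stress and markers of other cell types that a tumour sort could hold, and 10 genes stand in more than 1 list. A list's median log2 ratio was set against 10000 random lists of the same size drawn within 20 bins of mean expression. Lists with fewer than 5 measured members are given by member. The same procedure was applied to the absolute log2 ratios of genes within 10 Mb of Cd36. Shares of counts carry exact binomial 95% intervals.

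The steps were tested on simulated data for the 2 libraries, with counts drawn for the real genes from their mean levels and the real library sizes and 200 genes changed by known folds, 50 per fold, over 12176 measured genes. The 2-fold rule called 2% of genes changed 1.5-fold, 98% of those changed 2.5-fold and 100% of those changed 4-fold and 8-fold, and 0 unchanged genes. The intervals held the true ratio for 95.8% of genes, and 0 of 20 unchanged lists lay outside the central 95% of random lists. The counts were Poisson draws from a profile shared by both libraries, without variation between animals, sorts or preparations. These values thus check the steps under counting error alone and give no rate of false calls for the real libraries.

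Alternatives were DESeq2 1.42.0 size factors, total counts alone, log2(TPM + 1) of the deposited TPM averaged over lanes, other CPM minimums and fold sizes, protein-coding genes alone, equal depth, leaving out each lane, and 5 and 20 Mb windows. Tests with lanes as replicates, by edgeR's quasi-likelihood test with and without lane number as a block and by DESeq2, compare these libraries and not the genotypes, because their p-values measure re-sequencing of the same libraries. A correction for gene length and expression and the removal of genes under 300 bases were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.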

Results

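RNA was measured in cells sorted as CD8 T cells from B16 tumours of wild-type C57BL/6 mice and of Cd36 knockout mice. B16 is a mouse melanoma cell line. The cells were injected intravenously, and the tumours grew for 14 days. Cd36 encodes a scavenger receptor that takes up long-chain fatty acids and oxidised lipoproteins. The titles of the 8 deposited samples gave 4 sequencing lanes of 1 library per genotype, here called the WT and the CD36_KO library. Each WT lane held 2497048 to 2538468 estimated counts and each CD36_KO lane 2569962 to 2611740, which gave library totals of 10071960 and 10363391. The question set by the series design was how tumour-infiltrating CD8 T cells of the knockout differ from those of the wild type. With 1 library per genotype no difference has a replicate check. All intervals cover counting error only, and they treat reads as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error.

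The targeted gene was examined before all others. Cd36 (ENSMUSG00000002944.15; GRCm38 chromosome 5, 17781690 to 17888801) had 1194 counts in the WT library and 358 in the CD36_KO library. Its scaled abundance was 126.9 CPM (counts per 1000000 of the scaled library size) against 32.3 CPM, a log2 ratio of -1.98 (95% counting interval -2.15 to -1.80). The knockout library thus held 25.4% of the WT level (22.5 to 28.6). The 4 WT lanes held 287, 299, 307 and 301 counts, and the 4 CD36_KO lanes 107, 86, 88 and 77. Before composition scaling this was 119 ± 3.71 CPM against 34.5 ± 4.63 CPM (SD over 4 lanes of 1 library). The lanes of the genotypes did not overlap, and the direction went with the labels. On the log2(TPM + 1) scale the ratio was -1.25. In the same libraries the melanoma list had a median log2 ratio of -2.16 and the macrophage list one of -0.33. By transcript, the isoform of 2677 bases had an estimate of 538.5 counts against 23.0 and the isoform of 2564 bases 433.1 against 162.7. The isoform of 3399 bases stood at 62.5 against 85.3. These estimates divide reads among overlapping isoforms and are less certain than the gene total.

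Across the transcriptome, the CD36_KO library was poorer in melanoma and collagen transcripts and richer in transcripts of T cells, B cells, blood and liver. Of 12177 genes with a mean of at least 5 CPM, 792 were at least 2-fold higher in the CD36_KO library and 1314 at least 2-fold lower, leaving 10071 between. The protein-coding genes among them numbered 642 and 1167. This split depended on the scaling. It was 1114 higher and 940 lower with total counts alone, and 1501 higher and 329 lower on the TPM scale. The TPM calls used the log2(TPM + 1) ratio without the counting interval, so they differ from the main calls in more than scaling. The median log2 ratio of all measured genes was -0.13 with TMM scaling, 0.06 with total counts and 0.37 with TPM, so shifts of 0.20 and 0.50 lie between the scales. List medians below use TMM scaling. Each is given with its percentile among 10000 random gene lists matched on expression, a description of these libraries that a common shift leaves in place.

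The genes highest in the CD36_KO library were mostly known as products of the liver. Cyp2e1, a hepatic cytochrome P450, had 52 counts in the WT library and 513 in the CD36_KO library (log2 ratio 3.06, interval 2.65 to 3.50). Gc, the vitamin D binding protein, had 47 and 457 counts (3.04, 2.61 to 3.51), and Apob, the apolipoprotein of low-density lipoprotein, 185 and 1576 (2.85, 2.63 to 3.08). Serpina1e (3.04), Inmt (3.01), Serpina3k (2.93), Mug1 (2.89) and the thyroxine carrier Ttr (2.84) followed the same direction. The major urinary protein genes Mup14 (3.66), Mup11 (2.87), Mup20 (2.83) and Mup22 (2.80) are near-identical copies that share reads, so their separate values are uncertain. Mup14 moved to 5.13 without WT lane 4. On the log2(TPM + 1) scale Apob fell to 1.96, and the other genes named here ran from 2.62 (Mug1) to 3.83 (Mup14). A hepatocyte list of 24 genes, written after these values were seen, had 22 measured members, of which 21 were higher, 0 lower and 1 between. Its median was 2.58, and 2.44 over the 18 members outside the ranking of highest genes. Alb stood at 15.3 ± 0.84 TPM in the WT library and 147 ± 3.7 TPM in the CD36_KO library (SD over 4 lanes).

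The genes lowest in the CD36_KO library included Mt2, Arg1 and Sox10. The metallothionein gene Mt2 had 513 counts in the WT library and 63 in the CD36_KO library (log2 ratio -3.26, interval -3.67 to -2.88). Arg1, an arginase of tumour macrophages, had 6010 and 1155 (-2.62, -2.71 to -2.53), and Sox10, a transcription factor of the melanocyte lineage, 791 and 152 (-2.62, -2.88 to -2.37). The heat shock gene Hspa1a (-2.81), the hypoxia-induced prolyl hydroxylase Egln3 (-2.60) and the mitochondrial coactivator Ppargc1a (-2.57) were also among the 12 lowest. Lower genes also included Lars2 (-2.95), Insc (-2.84), Gprc5b (-2.78), Plagl1 (-2.77) and Fbln2 (-2.60). On the log2(TPM + 1) scale, where the added 1 draws genes of few TPM towards 0, the genes named here ran from -2.5 (Mt2) to -1.05 (Fbln2), with Insc at -1.77, Gprc5b at -1.72, Plagl1 at -1.68 and Egln3 at -1.57. Hspa1a shares reads with its near-identical copy Hspa1b.

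CD8 T cell genes were higher and melanoma genes lower in the CD36_KO library. All 12 CD8 T cell list members were at least 2-fold higher, with a median of 1.77 (percentile 100). Cd8a had 522 and 2307 counts (1.91, 1.77 to 2.05), Cd8b1 302 and 1380 (1.95), Cd3g 117 and 663 (2.26) and Trbc2 306 and 1392 (1.95). All 14 melanoma list members were at least 2-fold lower, with a median of -2.16 (percentile 0) and a range of -2.62 to -1.65. The median was -1.58 in TPM. The pigment genes Tyr (-2.40), Oca2 (-2.48) and Mlana (-2.39) lay near the low end, and Gpnmb, the most abundant member, had 12994 against 4893 counts. In both libraries melanoma transcripts were abundant beside those of T cells. Dct, a melanin synthesis enzyme, stood at 324 ± 11 TPM and Cd8a at 10.6 ± 0.48 TPM in the WT library, a ratio of 30.7. In the CD36_KO library Dct stood at 104 ± 2.4 TPM and Cd8a at 59.0 ± 1.2 TPM, a ratio of 1.76. Lyz2, the lysozyme gene of macrophages, exceeded Cd8a 124-fold and 25.8-fold.

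**Figure D1:**
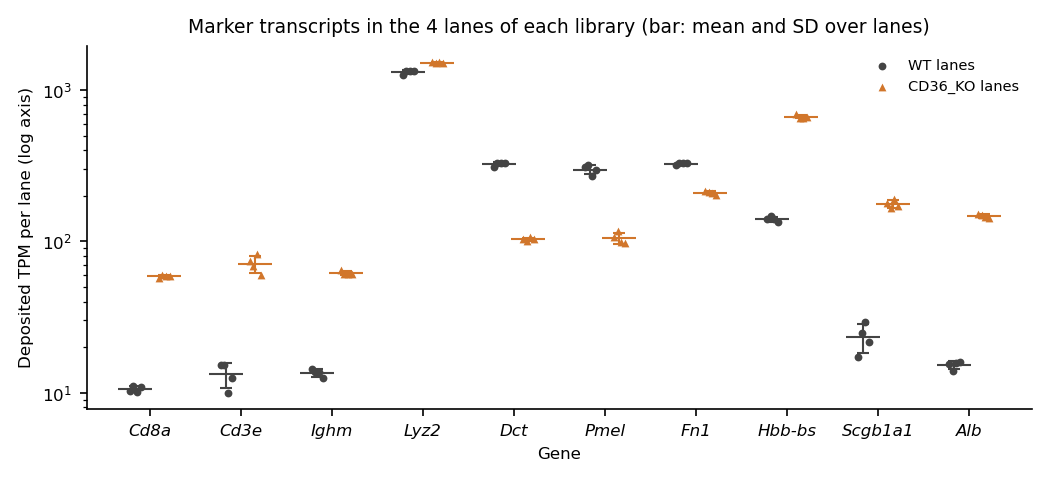
Deposited TPM (log axis) of 10 marker genes in the 4 lanes of the WT library (circles) and of the CD36_KO library (triangles), with bars for the mean and SD over lanes of 1 library. Cd8a stands at 10.6 and 59.0 TPM and Dct at 324 and 104 TPM. Lyz2 is higher in the CD36_KO library in TPM and lower in scaled counts (log2 ratio -0.36), and relative to the median of all measured genes it stands at -0.16 and -0.23.

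Markers of other cell types moved in different directions. B and plasma cell genes were higher, with 8 of 10 measured members at least 2-fold higher, 0 lower and 2 between (median 2.37, percentile 100, and 1.69 in TPM). Ms4a1, which encodes CD20, had 23 and 189 counts (2.80), and Ighd (2.79), Pax5 (2.66) and Cd79a (2.61) were close to it. Of 8 neutrophil and mast cell genes 6 were higher, 0 lower and 2 between (median 1.64, percentile 100), among them S100a9 (2.19) and Retnlg (1.97). All 5 measured erythroid genes were higher (median 1.62, percentile 99.99, and 2.22 in TPM), with Hbb-bs at 1327 against 4822 counts. The haemoglobin genes are near-identical in pairs, and their summed share was 0.0323% of counts against 0.111%. Lung epithelium genes had 5 of 9 members higher, 0 lower and 4 between (median 1.06, percentile 100), led by Cyp2f2 (2.86) and the club cell gene Scgb1a1 (2.24). NK and innate lymphoid genes had 3 of 5 higher, 0 lower and 2 between (median 1.12, percentile 99.63). Without genes under 20 CPM this median was 0.17, that of the B and plasma cell list 1.23 and that of the lung epithelium list 1.65. The NK and innate lymphoid median then rests on fewer than 5 genes, too few for a list median by the rule used elsewhere. The erythroid median was 2.6 after a correction for gene length and expression, added after seeing the data.

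Fibroblast and pericyte genes were lower, with 7 of 11 members at least 2-fold lower, 1 higher and 3 between (median -1.23, percentile 0.01, and -0.67 in TPM). The collagen genes Col1a1 (-2.32), Col1a2 (-2.21) and Col3a1 (-2.20) led the list. Its 1 higher member, Thy1 (1.5), is also a T cell gene. Macrophage and monocyte genes had 3 of 17 members lower, 0 higher and 14 between, with a median of -0.33 inside the range of random lists (percentile 18.68). Arg1 (-2.62), Cd14 (-1.31) and Adgre1 (-1.26) were the lower members, and Ccr2, a receptor of recruited monocytes, had a value of 0.92. Dendritic cell genes had 1 of 11 lower, the actin-bundling gene Fscn1 (-2.31), 0 higher and 10 between (median -0.22, percentile 35.17). On the TPM scale the macrophage and dendritic cell medians were 0.25 and 0.15, which is -0.12 and -0.22 relative to the median of all measured genes, and with the same correction the macrophage median was 0.14. Endothelial and platelet genes had 2 of 10 higher, the platelet genes Itga2b (1.53) and Ppbp (1.47), 1 lower, Pf4 (-1.01), and 7 between (median 0.48, percentile 99.72). The 5 measured CD4 T cell and Treg genes were all between, with a median of 0.25 (percentile 83.64). Over genes of at least 20 CPM, which were fewer than 5, it was -0.08. Cd4 itself had 85 and 119 counts (0.25, -0.17 to 0.67). Of the gamma delta T cell genes 0 of 8 reached 5 CPM. Only 2 keratinocyte genes did, Sfn (1.13) and Perp (-0.14), and only 2 sex-linked genes, Xist (0.43) and Kdm5d (0.33), which has a similar copy on the X chromosome.

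**Figure D2:**
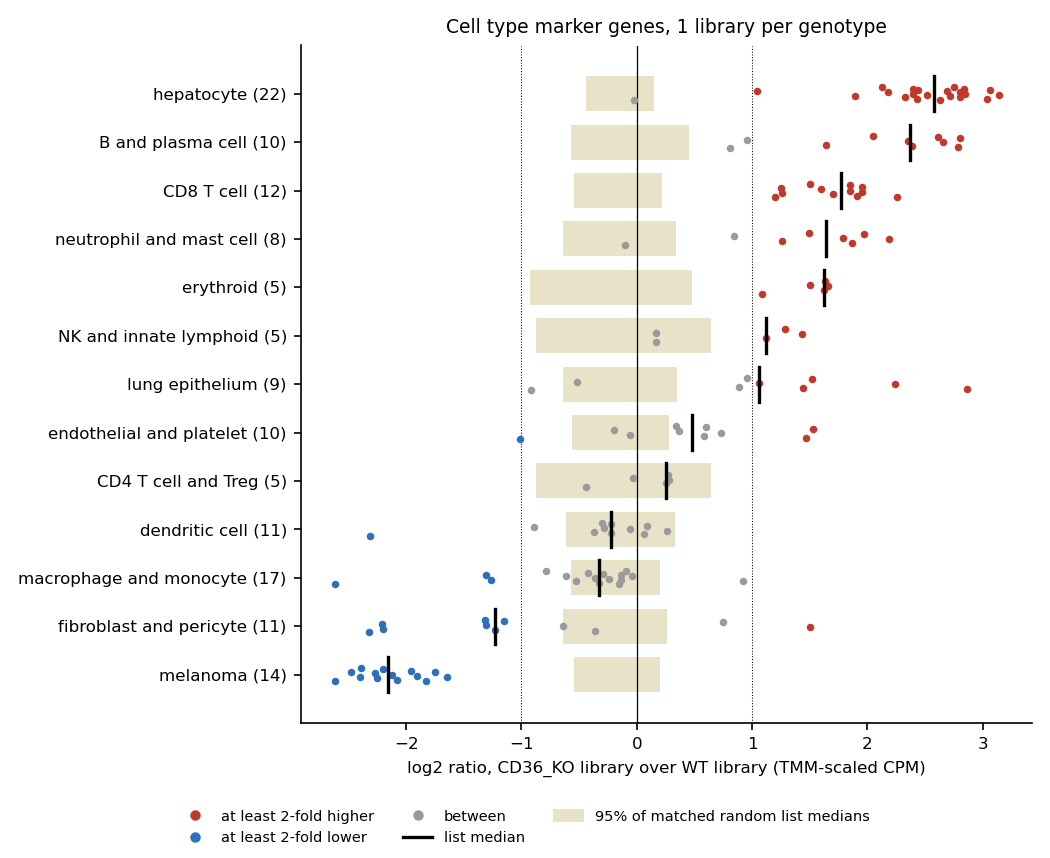
Log2 ratio (CD36_KO library over WT library, TMM-scaled CPM) of each measured gene in 13 cell type lists, coloured by the 2-fold rule, with the number of genes in brackets, the list median as a bar and 95% of matched random list medians shaded. The CD8 T cell list lies at a median of 1.77 and the melanoma list at -2.16, with 1 library per genotype. On the TPM scale the macrophage and dendritic cell medians become positive with the shift of all genes and stay below the median of all genes.

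T cell function lists were read beside the CD8 T cell median of 1.77. TCR signalling genes had 14 of 20 members higher, 0 lower and 6 between (median 1.27, percentile 100), and 1.23 over the 14 members that the CD8 T cell list does not hold. Themis, a regulator of thymocyte selection, had 239 and 1331 counts (2.24), and the zeta chain gene Cd247 114 and 481 (1.84). Naive, memory and stem-like genes had 15 of 23 higher, 0 lower and 8 between (median 1.21, percentile 100, and 1.81 in TPM). Lef1 (1.97), Slamf6 (1.78) and Cd28 (1.77) led this list, and Tcf7, the transcription factor TCF1, had 672 and 2258 counts (1.51). Cytotoxic effector genes had 11 of 18 higher, 2 lower and 5 between (median 1.17, percentile 100). Gzma (2.83), Ccl5 (2.34), Gzmb (2.11), Cx3cr1 (2.04) and the perforin gene Prf1 (1.79) were higher, and the lowest member stood at -1.57. The measured members summed to 1095 CPM in the WT library and 1149 CPM in the CD36_KO library. This sum weighs abundant members most and says little of the 11 higher genes. Lamp1, the most abundant member, stood at 97.4 TPM in the WT library and 95.9 TPM in the CD36_KO library. Tnf had 60 and 70 counts (-0.02), which is 0.12 relative to the median of all measured genes with TMM and 0.02 with TPM. Ifng, at 4 and 13 counts, was below 5 CPM.

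The exhaustion and inhibitory receptor list lay inside the range of random lists. Of its 15 measured members 2 were higher, 2 lower and 11 between, with a median of 0.08 (percentile 87.53), or -0.13 over genes of at least 20 CPM. Tox, a transcription factor of exhausted T cells, had 38 and 225 counts (2.33, 1.83 to 2.86), and Eomes had a value of 1.12. Nr4a3 (-1.63) and Tnfrsf9, which encodes 4-1BB (-1.36), were lower. Havcr2, which encodes TIM-3, had 217 and 216 counts (-0.24), which is -0.11 relative to the median of all measured genes with TMM and -0.12 with TPM. Pdcd1, which encodes PD-1, had 45 and 55 counts (0.05) and lay just under 5 CPM in the mean. Tissue residency genes had 2 of 13 higher, Itgae (1.90) and Cxcr6 (1.86), 1 lower, Rgs1 (-1.05), and 10 between (median 0.44, percentile 99.90). Interferon-stimulated genes had 2 of 24 higher, the guanylate-binding genes Gbp4 (1.36) and Gbp7 (1.33), 1 lower, the chemokine gene Cxcl10 (-1.90), and 21 between (median 0.24, percentile 99.81).

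Metabolic and proliferation lists were lower, beside a melanoma median of -2.16. Glycolysis genes had 13 of 18 members lower, 1 higher and 4 between (median -1.62, percentile 0, and -0.96 in TPM). Tpi1 (-2.14), Hk2 (-2.09), Pfkl (-1.91) and Pgk1 (-1.80) were the lowest of them. Cell cycle genes had 17 of 30 lower, 0 higher and 13 between (median -1.11, percentile 0, and -0.53 in TPM), led by Aurkb (-2.16), Ube2c (-1.86), the cyclin gene Ccnb1 (-1.78) and the ribonucleotide reductase gene Rrm2 (-1.72). Cholesterol synthesis genes had 5 of 20 lower, 0 higher and 15 between (median -0.76, percentile 0.01, and -0.18 in TPM), with Fdps (-1.49), Cyp51 (-1.40) and Msmo1 (-1.35) lowest. Relative to the median of all measured genes these list medians were -1.49, -0.97 and -0.63 with TMM and -1.33, -0.89 and -0.55 with TPM.

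Lipid genes were of interest because of the targeted receptor. These lists too stand beside a melanoma median of -2.16, with all 14 members lower, and a fibroblast median of -1.23, and the cells that their transcripts came from were not separated. Lipid uptake and storage genes had 6 of 27 members lower, 0 higher and 21 between (median -0.57, percentile 0.41, and -0.01 in TPM). Beside Cd36, these included the acyl-CoA synthetase gene Acsl3 (-2.22) and the lipid droplet genes Hilpda (-1.96) and Plin2 (-1.19). Fatty acid oxidation genes had 3 of 23 lower, 0 higher and 20 between, and their median of -0.34 lay inside the range of random lists (percentile 10.32) and was 0.19 in TPM. Ppargc1a (-2.57), Etfb (-1.07) and Cpt2 (-1.05) were the lower members. Ferroptosis and lipid peroxidation genes had 6 of 23 lower, 1 higher and 16 between (median -0.76, percentile 0.01, and -0.12 in TPM). Hmox1, which encodes haem oxygenase 1, had 2098 and 608 counts (-2.03), Alox15 4235 and 1410 (-1.82) and Ptgs2 129 and 54 (-1.49), and Alox12 was the higher member (1.79). Gpx4, which reduces lipid peroxides, had a value of -0.55, the cystine transporter gene Slc7a11 -0.73 and Acsl4 -0.72, all short of 2-fold. In TPM, Gpx4 (0.08) and Slc7a11 (0.13) were positive with the shift of all genes, and relative to the median of all measured genes they stood at -0.29 and -0.24 (-0.42 and -0.60 with TMM). Antioxidant and NRF2 target genes had 2 of 18 lower, Me1 (-2.09) and Prdx1 (-1.02), 0 higher and 16 between (median -0.49, percentile 1.53, and 0.05 in TPM). Relative to the median of all measured genes the antioxidant median was -0.36 with TMM and -0.32 with TPM, the lipid uptake median -0.43 and -0.38, the fatty acid oxidation median -0.20 and -0.17 and the ferroptosis median -0.62 and -0.49. Unfolded protein response genes had 4 of 18 lower, 0 higher and 14 between (median -0.65, percentile 0.32, and -0.07 in TPM), led by the asparagine synthetase gene Asns (-2.32). Early response and dissociation stress genes had 4 of 23 lower, 0 higher and 19 between (median -0.18, percentile 42.19), and relative to the median of all measured genes their median was -0.05 with TMM and -0.02 with TPM. The heat shock genes Hspa1b (-2.47) and Hspb1 (-1.93) and the immediate early gene Ier3 (-1.81) were lower with Hspa1a.

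**Figure D3:**
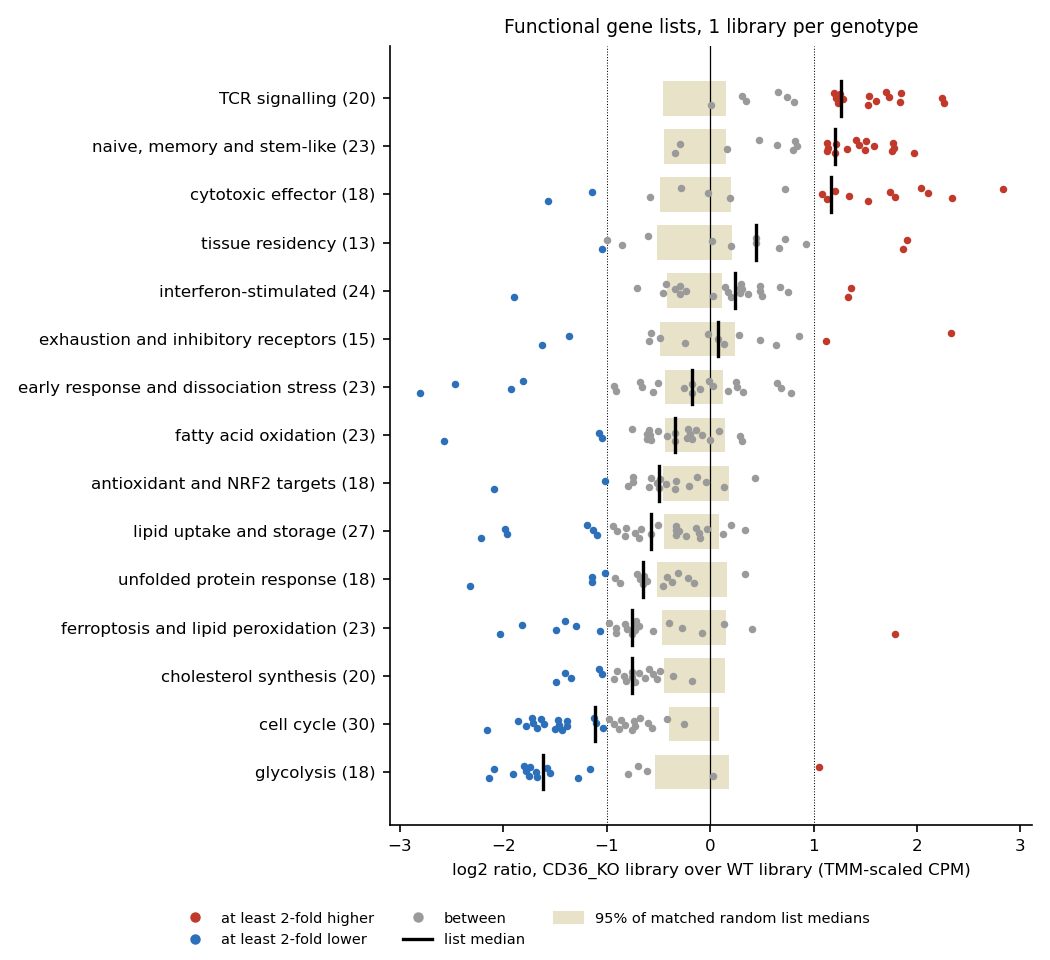
Log2 ratio (CD36_KO library over WT library, TMM-scaled CPM) of each measured gene in 15 functional lists, drawn as in the plot of cell type lists. TCR signalling lies at a median of 1.27 and glycolysis at -1.62. On the TPM scale all lists shift with the median of all genes, by which the fatty acid oxidation, antioxidant and early response medians become positive while staying below the median of all genes.

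Small nuclear and small nucleolar RNA genes were lower in the CD36_KO library. All 30 measured snRNA genes were at least 2-fold lower (median -4.14), as were 25 of 28 snoRNA genes (median -2.75) and 3 of 7 scaRNA genes (median -0.61). Many are near-identical copies, and the 65 genes of these classes held 46 distinct pairs of counts. Their summed share was 1.04% of counts in the WT library and 0.176% in the CD36_KO library. Mitochondrial ribosomal RNA made up 11.9% and 15.5%, ribosomal protein genes 1.41% and 1.73%, immunoglobulin genes 0.00702% and 0.0224%, and T cell receptor genes 0.0131% and 0.0469%. The 50 most abundant genes took 44.1% and 43.5%. Exact 95% intervals of these shares did not overlap between the libraries. Effective lengths implied a mean fragment of 160.6 bases in the WT library (159.8 to 161.1 over lanes) and 194.3 bases in the CD36_KO library (194.0 to 194.6). The kallisto settings behind them are not given. At a common depth of 10071960 counts, 29928 genes were detected in the WT library and 30234 in the CD36_KO library.

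**Figure D4:**
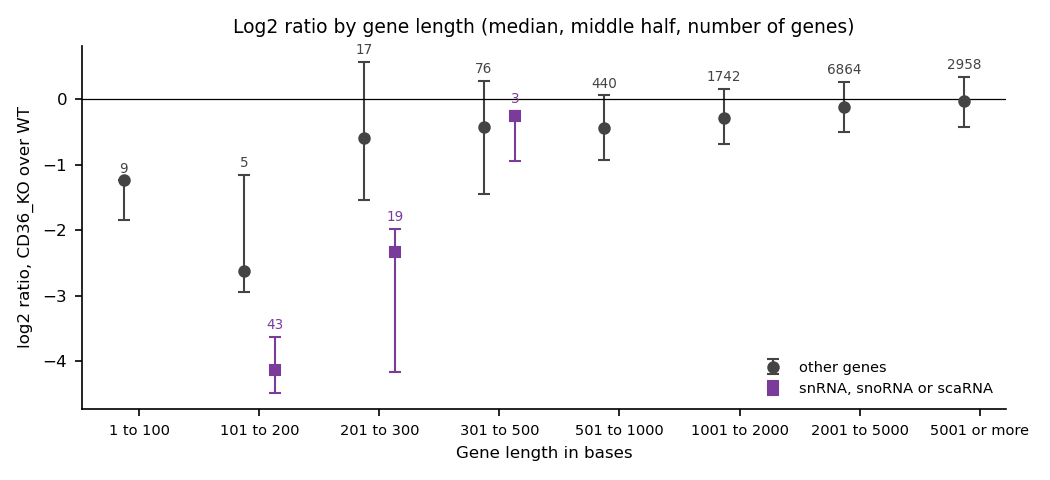
Median log2 ratio (CD36_KO over WT, TMM-scaled CPM) by gene length in bases, with bars for the interquartile range and the number of genes above each, for snRNA, snoRNA and scaRNA genes (squares) and other measured genes (circles). At 101 to 200 bases the medians are -4.14 and -2.63, and other genes of 5001 bases or more lie at -0.02.

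T cell receptor usage was broad in both libraries. Trbv segments held 162 counts in the WT library and 618 in the CD36_KO library, spread over 22 segments in each. The most used were Trbv16 and Trbv12-2 in the WT library at 10.5% each (exact 95% interval 6.23 to 16.3) and Trbv13-2 in the CD36_KO library at 10.4%. Trbv16 stood at 8.41% in the CD36_KO library (6.35 to 10.9), an interval that overlapped the one in the WT library. The sum of squared Trbv shares was 0.0647 and 0.0621. Trav segments held 111 and 393 counts, with sums of squared shares of 0.0239 and 0.0223. A difference in Trbv16 usage was not detectable at this depth.

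Genes near the targeted locus showed no excess in their median absolute log2 ratio. Within 10 Mb of Cd36 on chromosome 5, 58 measured genes had a median log2 ratio of 0.03, at percentile 95.6 of matched random gene sets. Of these genes 1 was at least 2-fold higher and 4 lower. Their median absolute log2 ratio was 0.45, at percentile 61.9 of matched random gene sets, whose central 95% ran from 0.31 to 0.57.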

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

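The tests of fewer tumour cells, of added blood RNA, of the correction for gene length and expression and of the source of remaining Cd36 transcript were chosen after the data were seen, and those of the small RNA genes before their results were. Implied fragment length is a signal outside the expression values: the effective lengths imply a mean fragment of 194.3 bases in the CD36_KO library and 160.6 bases in the WT library, with an SD over lanes of 0.25 and 0.61. The kallisto settings are not given. A length set once per library would not give the lane values of 194.0 to 194.6 and 159.8 to 161.1, each with an SD over long transcripts of at most 0.016. Of 22 sets of 4 lane values examined for a lane far from the others (totals, fragment length, Cd36 and composition shares), 0 held one.

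T cell genes were higher and melanoma genes lower in the CD36_KO library. Fewer tumour cells in an otherwise unchanged mix of cells would raise markers of every other cell type alike. The CD8 T cell median, however, lay 2.10 above the macrophage median, with no overlap of their interquartile ranges. Where the mix of other cells changed as well, this test cannot decide. The fibroblast and pericyte median was -1.23 and the lung epithelium median 1.06. A trend with gene length or expression left a gap of 3.77 between the CD8 T cell and melanoma medians after correction, against 3.93 before. More blood or lymphoid RNA may be part of the pattern, since the lowest of the erythroid, neutrophil and B cell medians was 1.62, but as the whole cause it would lower lung epithelium with melanoma, and these medians lay 3.22 apart. A mixture of both with a different sort purity stays open, as do fewer tumour cells in a changed mix of other cells. Different tissue around the tumours and an effect of the knockout on T cell infiltration stay open too. Genotype and library cannot be separated with 1 library each, and the CD8 sort should have removed all of these cells but T cells.

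Cd36 transcript was present in the CD36_KO library at 25.4% of the WT level. Wild-type B16 cells in the sorted material stay open as its source. The Cd36 ratio of -1.98 falls within the range of the melanoma genes (-2.62 to -1.65), whereas B16 transcript beside host transcript lost in the knockout would put it below the ratio of the B16 cells, which that range does not fix. If B16 cells supplied Cd36 in both libraries, its fall would owe nothing to the knockout. The isoform estimates did not move alike, at 538.5 against 23.0 and 62.5 against 85.3 counts, but they are too uncertain to decide. Transcription in host cells at the wild-type level stays open. For macrophages, the cells tested, it does so only through Arg1. The upper bound of the Cd36 ratio lay 0.82 above Arg1, the lowest macrophage gene, and macrophage genes ranged from -2.62 to 0.92. All other measured macrophage genes lay above the Cd36 interval of -2.15 to -1.80. The macrophage list median was -0.33, with an interquartile range of -0.61 to -0.14. The test did not use fibroblast and pericyte genes, whose ratios ranged from -2.32 to 1.5, so it does not speak on those cells. Transcript from the altered allele, which need not encode protein, remains open too, and so does a mixture of sources.

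Small nuclear and nucleolar RNA genes were lower in the CD36_KO library. Loss of nuclear RNA in general is argued against by the long nuclear RNAs Malat1 (-0.03), Xist (0.43), Kcnq1ot1 (0.53) and Neat1 (0.60). The tested set had a median of 0.07. It also held the snoRNA host genes Snhg1 (0.07), Snhg12 (-0.07) and Gas5 (-0.16), whose RNA need not be retained in the nucleus. Retention of shorter fragments in the WT library may account for part of the difference. The 29 other genes under 300 bases had a median of -1.24, against -3.91 for the small RNA genes, and the implied WT fragments were shorter. Some of these 29 genes have identical counts, so they are not independent. Fragment retention leaves part open: at 201 to 300 bases the small RNA genes had a median of -2.34 and other genes -0.59. No biological explanation was tested.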

How the results depend on the processing

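The tests with genes under 300 bases left out and with the length correction were chosen after seeing the data. The counts of 792 higher and 1314 lower genes moved by more than 1.5 times with the thresholds and with TPM. They were 2381 and 2471 with no CPM minimum, 1890 and 2056 at 1 CPM, 344 and 679 at 20 CPM, 1643 and 2826 at 1.5-fold, 147 and 264 at 4-fold, and 1501 and 329 with TPM, of which 709 and 329 were shared. The thresholds act by construction. TPM shifts the median of all genes by 0.50 and single genes by other amounts, and the cause was not tested. The TPM calls also leave out the counting interval and add 1 to each value. Cd36 kept its direction at -1.78 with total counts, which add 0.20 to every gene, and at -1.25 with TPM. The antioxidant list median was 0.05 with TPM through this shift, and stayed at -0.32 relative to the median of all genes (-0.36 with TMM). DESeq2 factors (815 and 1268), protein-coding genes alone (951 and 1179), equal depth (786 and 1303) and no genes under 300 bases (814 and 1234) stayed within 1.5 times. Leaving out each lane gave 795 to 878 higher and 1178 to 1324 lower genes and a Cd36 ratio of -2.06 to -1.91.

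The lanes share only a lane number: deviations from the library means correlated at -0.05 to 0.02 across genes for the 4 pairs of the same number, and 0 pairs exceeded 0.1. With lanes as replicates, edgeR's quasi-likelihood test called 967 higher and 1061 lower 2-fold genes, 969 and 1060 with lane number as a replicate block, and DESeq2 969 and 1056. At any fold, 7254 of 12177 genes had an edgeR adjusted p under 0.05. Of 35 splits of the lanes 1, the real split, gave as many, and the highest other split gave 0. Every other split mixes lanes of both libraries, so this outcome was set by the design and says nothing of genotype.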

Other observations

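Among T cell programmes, distances from the CD8 T cell median do not depend on a common scaling factor. The TCR signalling median lay at -0.50, the naive, memory and stem-like median at -0.56 and the cytotoxic median at -0.60 relative to the CD8 T cell median. Tissue residency lay at -1.33, the CD4 T cell and Treg list at -1.52 and the exhaustion list at -1.69. Within the exhaustion list the genes separated, with Tox at 2.33, above the CD8 T cell median of 1.77, and Nr4a3 at -1.63 and Tnfrsf9 at -1.36. Which cells these transcripts came from was not tested.

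Other tissue and RNA classes differed as well. Long non-coding RNA genes had 63 members higher and 28 lower of 434 measured (median 0.31), against -0.17 for protein-coding genes. Signal recognition particle and other genes of the misc_RNA class took 8.62% of counts in the WT library and 6.29% in the CD36_KO library, and ribozyme genes 0.852% and 0.438%. The vault RNA gene Vaultrc5, chosen after its values were seen, had 364 and 15 counts (-4.84). Mitochondrially encoded mt-Atp8 (204 bases) had 6449 and 1619 counts (-2.23), and mt-Nd4l (297 bases) had 9405 and 10124 (-0.13). This pair was likewise chosen afterwards. Its lengths are annotated gene lengths, and no trend with length can be read from it. Transcripts of the Y-linked genes Ddx3y (6 and 29 counts) and Eif2s3y (2 and 12) were near the floor, beside 8137 and 12923 counts of Xist.

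It was tested as a hypothesis, before the values were seen, that sequence derived from another strain around the knocked-out locus may alter the expression of neighbouring genes. The median absolute log2 ratio of genes within 10 Mb lay at percentile 61.9 of random sets, so no excess of this median was found in these libraries. It was 0.41 within 5 Mb and 0.42 within 20 Mb. A median over 58 genes would not show effects on a few neighbours. The random sets, at 0.31 to 0.57, carry the broad differences between the libraries.

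The hepatocyte genes had a median of 2.58, and the source of these transcripts was not determined. Trf, the list member with the most counts and one transcribed in many tissues, had a value of -0.02, which is 0.11 relative to the median of all measured genes. Alb exceeded Cd8a 1.44-fold in the WT library and 2.497-fold in the CD36_KO library, so liver transcripts were present in both.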
